A study of Mus musculus with 13 samples.

How the data were processed

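RNA was sequenced from adrenal glands of C57BL/6 mice in which TAM induction removes Star, the gene of the protein that brings cholesterol to the inner mitochondrial membrane for steroid synthesis. The 13 libraries fall into 3 groups by the labels, 5 from before TAM, 4 from 24 hours after it and 4 from 8 weeks after it. The labels give each library a number within its group and do not say whether each came from a separate animal, so p-values measure the spread between these samples. The samples analysed here include no mice that received TAM without the deletion, so time, TAM and the loss of Star cannot be separated by this design. Libraries were made with a stranded mRNA kit, per the labels' protocols. Reads were handled with bcl2fastq 2.17 and TopHat2 2.0.14 on mm10 (GRCm38), per the submitters' processing notes.

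The deposited tables give, for each RefSeq transcript and library, an expected count (an estimated count of reads that need not be whole) and FPKM, per the file headers. Between 43.3% and 46.4% of the counts per library were whole numbers to within 1e-06. In the deposited tables FPKM equals the expected count divided by transcript width and by 1 total per library, as recomputed from the values, so the libraries were not scaled against each other. A further deposited table compares 8 weeks with before, with log2 values of FPKM, a log2 ratio, a p-value and a q-value per the file headers. Recomputing the authors' p-value from the deposited log2 values with an equal-variance test returned it within 1% for 100.0% of transcripts. The log2 values hold a pseudocount of 0.0001 by their size.

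The listed transcripts met a filter that was read from the values, since it is not given in the sources used here. Each had at least 16 reads in 4 or more of the before libraries or in 3 or more of the later group tabulated with them. The before and 8-week tables listed 19655 transcripts and the 24 h libraries 19191, of which 18738 were shared, for 14078 genes. A gene that rose from a low level at 8 weeks only is therefore absent from the fit of all libraries, which covers the shared transcripts. Listed totals ran from 17331673 to 27309429 reads per library, and the totals implied by FPKM from 19272728 to 31358164, so the listed transcripts held 86.5% to 93.0% of the implied reads. Paralogs and near-identical copies share reads under this counting, so values of kallikrein, MHC, metallothionein, Hsd3b and Cyp11b family members carry that uncertainty. Coordinates are 1-based on mm10. The symbols of 10746 single-transcript genes were compared with a GRCm38 annotation, and 99.8% lay on the same chromosome.

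Expected counts were summed per gene and rounded to whole numbers. Genes were tested with edgeR 4.0.16 (R 4.3.3), its quasi-likelihood test with TMM scaling and filterByExpr, in 1 fit of all 13 libraries without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. All p-values printed for genes come from that test unless another is named, and standard errors are the fold change divided by the root of its F statistic. Star transcript models were compared on FPKM with two-sided exact permutation tests, adjusted over the 12 tests of that family. The comparisons were 8 weeks with before, which the series design names, 24 h with before, and 8 weeks with 24 h. Gene lists (30 lists, 367 members, 335 of them among the shared genes) were fixed before the data were examined, and 27 lists with at least 3 tested members were tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and limma fry, whose directional p asks whether the members move on balance one way. Counts of list members called are over all genes tested and adjusted over the list alone.

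Genes named in the text follow a rule also fixed before the data were examined: Star, then per comparison the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, with a mean of at least 5 CPM in the higher group, then 2 to 4 members per list in order of p. Where no member of a list was called, its lowest-p gene was included in the tests of alternatives. Results of 2 genes that the rule names are not reported here. Genes named outside the rule were chosen after their values were seen and are said to be. Simulated data had the real library sizes, with the mean and spread of each gene taken from the before libraries alone. For 8 weeks against before, 64% of genes changed 2-fold and 92% of those changed 4-fold were called, with 7 false calls among 13829 unchanged genes. By camera 2 of 2 shifted lists and 0 of 25 others were called. Simulated genes were drawn independently, so this list test cannot speak for lists whose members move together. In the real libraries the estimated correlation ran from 0.04 (clock) to 0.899 (fat cells). The shares of genes called were 62% and 90% for 24 h against before, with 12 false calls. For 8 weeks against 24 h 0 of 14029 unchanged genes were called by edgeR. The real 24 h libraries differed more from each other than those from before (lowest median correlation within the group 0.811 against 0.945). The simulated shares and false calls therefore need not hold for the real libraries. Alternatives were DESeq2 1.42.0, RLE scaling, no filter, a filter of 5 CPM in 4 libraries, only the 2 groups compared, a replicate block, voom with quality weights, a 2-fold threshold and each library left out in turn. Since filterByExpr removed none of the 14078 shared genes, the fit without a filter repeated the main fit and checks nothing. A covariate for sex read from Y-linked genes was not run, since those genes are not listed, and none was read from Xist instead. Comparing pairs within groups by a chi-square test of counts, the lowest value per gene was 18.3 (before replicates 4 and 5), so no library was counted as a repeat of another. Figures were drawn with matplotlib.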

Results

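Messenger RNA was measured in mouse adrenal glands before TAM (5 libraries), 24 hours after it (4 libraries) and 8 weeks after it (4 libraries). The adrenal gland holds a steroid-making cortex with an outer zona glomerulosa, a catecholamine-making medulla, and a capsule, vessels and immune cells. Listed reads per library ranged from 17331673 to 27309429. Gene levels are FPKM as deposited, with the SD over libraries.

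Star, on chromosome 8 from 25808513 to 25816119 of mm10 (plus strand), is the gene the study deleted, so its level was read first. Star stood at 3797 ± 399 FPKM before TAM (n = 5), 334.7 ± 274 at 24 h (n = 4) and 146.1 ± 50.8 at 8 weeks (n = 4), and every later library lay below every library from before. The log2 fold change was −3.39 (SE 0.74, adjusted p = 0.0069) at 24 h and −4.56 (SE 0.78, adjusted p = 0.00076) at 8 weeks. Between 8 weeks and 24 h the log2 difference was −1.17 (SE 0.69, adjusted p = 0.24). Without 24 h replicate 3, that difference was −1.62 with an adjusted p of 0.0064, and without 24 h replicate 2 it was −0.68 with an adjusted p of 0.53. Replicate 3 at 24 h had the lowest Star (17.4 FPKM), but its steroid synthesis list also stood at −5.07 log2 relative to before. Its Star level therefore cannot check the deletion. Without that library Star stood at 440.4 ± 213 FPKM at 24 h (n = 3). Other cortical genes, such as Hsd3b1 and Nr5a1, fell at 8 weeks too, so the Star level alone does not check the deletion there.

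The tables split Star into 3 transcript models on the same span, named with a deletion, without it and as the RefSeq entry. The 2 models without the deletion together gave 3471 ± 452 FPKM before, 28.9 ± 22.7 at 24 h and 81.8 ± 48.8 at 8 weeks (exact permutation test against before, p = 0.016 and 0.032 adjusted over 12 tests at both times). The model with the deletion gave 327 ± 168 FPKM before, 306 ± 254 at 24 h and 64.3 ± 28.6 at 8 weeks, with exact permutation p = 0.89 at 24 h and 0.063 at 8 weeks against before. The share of Star FPKM in the model with the deletion was 8.74 ± 4.77% before, 86.8 ± 8.57% at 24 h and 46.9 ± 22.0% at 8 weeks (exact permutation test against before, p = 0.016 at both times). The share at 8 weeks was below that at 24 h in every library (exact permutation p = 0.029, adjusted p = 0.05 over 12 tests). Reads common to the models are assigned by estimate, so a share in the before libraries need not be a deleted transcript. Before replicate 2 had 3714.5 FPKM in the RefSeq entry and 0.3 in the model named without the deletion. In the other before libraries nearly all FPKM without the deletion lay in the latter model.

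**Figure D1:**
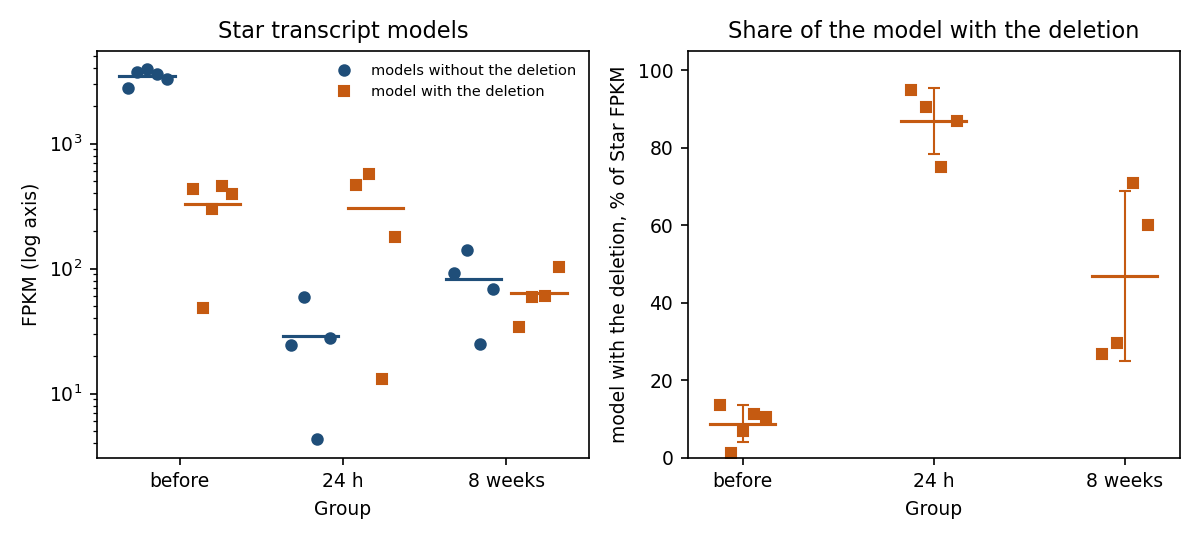
Star transcript models per library. Left, FPKM on a log axis of the models without the deletion (circles) and the model with it (squares), and right, the percent of Star FPKM in the model with the deletion. Points are libraries, lines are means and the bars at right are SD. The share rose from a mean of 8.74% before to 86.8% at 24 h.

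The comparison of 8 weeks with before, named in the series design, asks which genes differ once the deletion has lasted. By single genes, 12 of 12 listed genes of lipid-laden macrophages, 14 of 15 of macrophages and 11 of 12 of lymphocytes rose. Of the cortical lists, 9 of 14 zona glomerulosa, 6 of 11 steroid synthesis and 5 of 10 cortical identity genes fell. Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 17.9 ± 17.3 (n = 5) to 1038 ± 234 FPKM (n = 4), and Akr1d1, a steroid 5-beta-reductase, fell from 953 ± 384 to 4.14 ± 6.65 FPKM. Of 14078 genes tested, 5193 were called, 2882 higher and 2311 lower, and without a scaling factor 2424 higher and 3054 lower, with the median of all genes moved by −0.127 on the log2 scale.

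All 12 listed genes of lipid-laden macrophages rose (12 adjusted over the list alone), with a median log2 fold change of 4.44 (camera adjusted p = 7.3e-11, and adjusted p = 0.35 with an estimated correlation). Spp1, the gene of osteopontin, rose from 26.6 ± 7.65 to 889 ± 289 FPKM (log2 fold change 5.18, SE 0.37, adjusted p = 4.7e-06), and Fabp5, a fatty acid carrier, from 37.2 ± 13.6 to 914 ± 141 FPKM. Of 15 macrophage genes, 14 rose (14 adjusted over the list alone, camera adjusted p = 1.1e-08, and adjusted p = 0.38 with an estimated correlation), among them the lysosomal protease gene Ctss, from 118 ± 50.8 to 1892 ± 437 FPKM. Of 12 lymphocyte genes, 11 rose (11 adjusted over the list alone, camera adjusted p = 7.5e-05, and adjusted p = 0.45 with an estimated correlation), with Ptprc at log2 2.48 (SE 0.24) and Cd4 at 3.13 (SE 0.33). All 7 MHC class II genes rose (7 adjusted over the list alone, camera adjusted p = 0.00037, and adjusted p = 0.45 with an estimated correlation), among them H2-DMb1 and H2-Aa, whose family shares reads and is uncertain in that respect.

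Of 11 genes of steroid synthesis, 6 fell and 1 rose (7 and 1 adjusted over the list alone), with a median log2 fold change of −1.99 (camera adjusted p = 0.029, and adjusted p = 0.61 with an estimated correlation). The camera adjusted p was 0.052 without 8-week replicate 3 and 0.051 without a scaling factor. Hsd3b1, which makes progesterone from pregnenolone and has near-identical copies that leave its value uncertain, fell from 7200 ± 674 to 649 ± 289 FPKM (log2 −3.37, SE 0.38, adjusted p = 3.7e-05). Fdxr, which feeds electrons to the mitochondrial P450 enzymes, fell by 2.76 on the log2 scale, and Cyb5a rose by 1.30. The side-chain cleavage enzyme gene Cyp11a1 fell by 1.99 on the log2 scale (SE 0.45). Of 14 zona glomerulosa genes, 9 fell and 2 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.00093, and adjusted p = 0.45 with an estimated correlation). Dab2 fell from 218 ± 21.4 to 25.4 ± 4.75 FPKM and Wnt4 from 86.1 ± 26.5 to 5.00 ± 2.02 FPKM. Of 10 genes of cortical identity, 5 fell (5 adjusted over the list alone, camera adjusted p = 0.029, and adjusted p = 0.45 with an estimated correlation, or 0.081 with only these groups in the fit, 0.051 without a scaling factor and 0.052 without 8-week replicate 3). In it the steroidogenic factor gene Nr5a1 fell from 278 ± 22.8 to 25.1 ± 12.1 FPKM and Gata6 from 22.5 ± 3.16 to 7.58 ± 1.33 FPKM.

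Capsule and fibroblast genes rose in 9 of 10 cases (9 adjusted over the list alone, camera adjusted p = 8.9e-05, and adjusted p = 0.35 with an estimated correlation), including Dcn, from 131 ± 89.7 to 757 ± 222 FPKM. Fibrosis genes rose in 7 of 12 cases and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.45 with an estimated correlation), with Col5a2 and Lox leading. Of 21 respiratory chain subunits, 13 rose (15 adjusted over the list alone, camera adjusted p = 0.00026, and adjusted p = 0.61 with an estimated correlation), among them Cox6c at log2 1.20 (SE 0.19). The brown fat genes Ucp1, chosen here after its values were seen, and Cidea stood at 34.1 ± 41.1 and 27.3 ± 27.2 FPKM before and at 769.8 ± 474 and 330.1 ± 178 FPKM at 8 weeks. In 8-week replicates 1 to 4 the mean of the respiratory chain list was 0.71, 0.72, 0.25 and 0.99 log2 relative to before, and Ucp1 stood at 508.3, 943.2, 278.8 and 1349 FPKM. Of 14 genes of lipid storage, 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.049, and adjusted p = 0.61 with an estimated correlation). This list was not called without before replicate 1 or 8-week replicates 1, 3 or 4 (camera adjusted p = 0.073, 0.055, 0.062 and 0.061). Dgat1, which makes triglycerides, rose by log2 2.25, and Soat1, which makes cholesterol esters, fell by 1.39. The lipid storage list was lowest within its group in before replicate 1 (−1.21 log2 relative to before) and in 24 h replicate 3 (−1.86). The fat-cell list was lowest in the same libraries (−4.42 and −6.26), so a change in lipid storage is not separated here from the share of fat cells. Fat-cell genes rose in 5 of 10 cases (9 adjusted over the list alone, camera adjusted p = 0.054, and adjusted p = 0.76 with an estimated correlation), with Fabp4 from 695 ± 298 to 5792 ± 2264 FPKM, and on this list before replicate 1 stood at −4.42 log2 relative to the before mean, with the next before library at 0.77. The fat-cell list was called with only these groups in the fit (9 of 10 rose, camera adjusted p = 0.014) and without any 1 of before replicates 2 to 5, 24 h replicate 3 or 8-week replicate 2 (camera adjusted p from 0.0067 to 0.046). Without a scaling factor it was called too (0.02), against adjusted p = 0.76 with an estimated correlation in all libraries. Cholesterol transfer genes included rises of the lysosomal carriers Npc2 (log2 1.81, SE 0.16) and Npc1 and falls of Osbp and Gramd1b, 4 and 2 of 12 (5 and 2 adjusted over the list alone, camera adjusted p = 0.74). The median of that list was 0.23 and its mean −0.02.

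Several other lists were not called. LXR targets, genes that answer to oxysterols, rose in 6 of 10 cases and fell in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.06, and adjusted p = 0.61 with an estimated correlation), and were called without any 1 of before replicates 3, 4 or 5, 24 h replicate 3 or 8-week replicate 2 (camera adjusted p from 0.036 to 0.05) and without a scaling factor (0.043). The targets that rose included Mylip at log2 1.24 and Abcg1 at 2.07. Glucocorticoid-induced genes rose in 5 of 11 cases (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.22), NRF2 targets in 5 of 12 (5 and 1 adjusted over the list alone, 0.26). Targets of p53 rose in 5 of 12 with 1 lower (5 and 2 adjusted over the list alone, 0.3). Interferon genes rose in 4 of 12 cases (4 adjusted over the list alone, camera adjusted p = 0.31). Endoplasmic reticulum stress genes rose in 2 of 15 (1 adjusted over the list alone, 0.29), where Atf3 rose by log2 4.25. Clock genes rose in 1 of 15 cases and fell in 2 (1 and 2 adjusted over the list alone, camera adjusted p = 0.31). Genes of the ACTH response rose in 3 of 15 and fell in 2 (3 and 3 adjusted over the list alone, 0.98). Cholesterol synthesis genes rose in 3 of 22 and fell in 4 (2 and 0 adjusted over the list alone, 0.62). Of 13 proliferation genes 1 fell, Mcm2 (1 adjusted over the list alone, camera adjusted p = 0.31). Of 3 X-zone markers 1 fell, Thrb (1 adjusted over the list alone, 0.44). Of 2 gonad genes tested Sox9 rose (log2 1.08, SE 0.30, adjusted p = 0.014, 1 adjusted over the list alone), and it was not called without 8-week replicate 1 (adjusted p = 0.061). Of 2 liver and kidney genes 0 were called by edgeR (0 adjusted over the list alone) or DESeq2 and 1 passed an unadjusted p under 0.05. Red blood cell genes had 0 of 5 called by edgeR (0 adjusted over the list alone), 0 by DESeq2 and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.62).

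The other largest rises were Mcoln3 (0.0427 to 4.70 FPKM), Klk1, Atp6v0d2, Mmp3, Htr2b, Il7r and Mmp12. Klk1 rested on 8-week replicate 1 (134.4 FPKM against at most 5.49 in the others), and without it the log2 fold change was 2.84 with an adjusted p of 0.10. It belongs to a family of near-identical genes and its value is uncertain. The largest falls were Akr1d1, Nr0b1, Mybpc1, Srd5a2, A2m, Vsnl1, Shh and Oca2. Nr0b1, a repressor of steroidogenic gene expression, fell from 12.1 ± 4.59 to 0.0711 ± 0.0580 FPKM. Mybpc1 held 3 reads in all over the 4 libraries at 8 weeks against 668 over the 5 from before. A2m was high in before replicate 1 alone (59.13 FPKM, next 6.753), and its log2 fold change went from −5.51 to −3.37 without it.

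Medulla markers had a median log2 fold change of 1.42 with 0 of 15 called (edgeR, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 by DESeq2, camera adjusted p = 0.14, and adjusted p = 0.82 with an estimated correlation). With only the before and 8-week libraries in the fit, 13 of 15 were called higher (camera adjusted p = 0.00036), and without 24 h replicate 3 alone 2 were (camera adjusted p = 0.038). The fit of all libraries included 24 h replicates 3 and 4, where the mean of these markers stood at −5.29 and −3.95 log2 relative to before. Of 10 endothelial genes 1 fell, Flt1 (0 adjusted over the list alone, camera adjusted p = 0.49). Flt1 was not called when any 1 before or 8-week library was left out (adjusted p from 0.06 to 0.1). Bulk RNA does not separate a change in the share of a cell type from a change within its cells. By camera 11 of 27 lists were called, 0 of them with an estimated correlation (3 at an unadjusted p under 0.05) and 14 by fry, and 33 of 100 splits of the same libraries gave at least 11.

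With only the 2 groups in the fit, 7444 genes were called on the shared transcripts and 7895 on all transcripts listed for both groups. The authors' deposited table lists 2374 transcripts higher and 1636 lower at a q-value under 0.05 and at least a 2-fold change, and of its 3398 genes tested here 2417 were also called at 2-fold in the same direction. Star is not among the authors' calls. Its model without the deletion, RefSeq entry and model with the deletion have q-values of 0.46, 0.32 and 0.064 there (log2 ratios −3.0, −5.01 and −2.11).

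**Figure D2:**
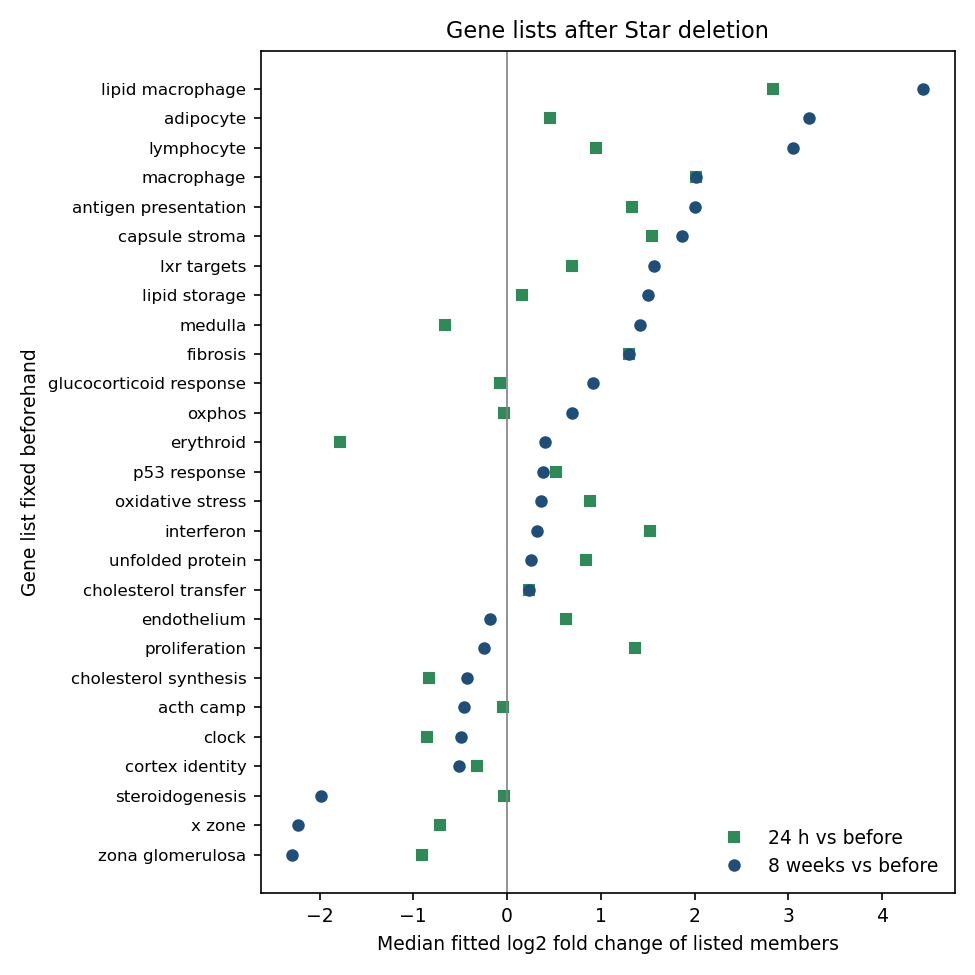
Median fitted log2 fold change of the members of each gene list, at 24 h (squares) and at 8 weeks (circles) against before. Lipid macrophage had a median of 4.44 at 8 weeks and zona glomerulosa −2.29.

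The comparison of 24 h with before addresses the early response. By single genes, 12 of 15 macrophage, 9 of 12 interferon and 9 of 15 endoplasmic reticulum stress genes rose, while 5 of 14 zona glomerulosa and 5 of 22 cholesterol synthesis genes fell. Cd5l, a macrophage protein, rose from 2.60 ± 1.81 (n = 5) to 162 ± 140 FPKM (n = 4), and Slc7a11, the cystine transporter, from 0.151 ± 0.00792 to 5.08 ± 3.36 FPKM. Of 14078 genes, 2708 were called, 1774 higher and 934 lower. Without 24 h replicate 3, 2341 were called higher and 1657 lower, and with quality weights 2849 and 2529.

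Of 12 genes of lipid-laden macrophages, 11 rose (11 adjusted over the list alone, camera adjusted p = 7.6e-11, and adjusted p = 0.23 with an estimated correlation), including Fabp5 (37.2 ± 13.6 to 331 ± 137 FPKM) and Spp1. Of 15 macrophage genes, 12 rose (13 adjusted over the list alone, camera adjusted p = 7.6e-11, and adjusted p = 0.23 with an estimated correlation), with Fcgr1 at log2 3.08 (SE 0.29, adjusted p = 0.00011). Of 12 interferon response genes, 9 rose (11 adjusted over the list alone, camera adjusted p = 7.1e-07, and adjusted p = 0.28 with an estimated correlation), among them Oasl2 (14.2 ± 3.04 to 45.3 ± 12.8 FPKM) and Irf7. Of 15 endoplasmic reticulum stress genes, 9 rose (12 adjusted over the list alone, camera adjusted p = 8.6e-05, and adjusted p = 0.37 with an estimated correlation), with Atf3 at log2 3.64 (SE 0.40) and Trib3 at 3.81 (SE 0.63).

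Capsule and fibroblast genes rose in 7 of 10 cases (8 adjusted over the list alone, camera adjusted p = 1.8e-05, and adjusted p = 0.23 with an estimated correlation), including Pdgfrb. All 7 MHC class II genes rose (7 adjusted over the list alone, camera adjusted p = 0.00026, and adjusted p = 0.33 with an estimated correlation). LXR targets rose in 5 of 10 cases (5 adjusted over the list alone, camera adjusted p = 0.0013, and adjusted p = 0.33 with an estimated correlation), led by Mylip (log2 1.65, SE 0.13) and the cholesterol exporter Abcg1 (2.79, SE 0.25). Proliferation genes rose in 8 of 13 cases and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0017, and adjusted p = 0.48 with an estimated correlation), with Mki67 higher and Mcm2 lower, and the list mean was highest in replicate 3 (1.83 log2 above before). With only replicates 1 and 2 at 24 h, 1 of 13 proliferation genes was called, Mcm2, which was lower (camera adjusted p = 0.25). Fibrosis genes rose in 7 of 12 cases (7 adjusted over the list alone, camera adjusted p = 0.0023, and adjusted p = 0.33 with an estimated correlation). Lymphocyte genes rose in 2 of 12 (Cd4 and Ptprc, 2 adjusted over the list alone, camera adjusted p = 0.0037, and adjusted p = 0.43 with an estimated correlation), and NRF2 targets rose in 6 of 12 with 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0058, and adjusted p = 0.33 with an estimated correlation). Targets of p53 rose in 6 of 12 cases (6 adjusted over the list alone, camera adjusted p = 0.011, and adjusted p = 0.43 with an estimated correlation), with Gdf15 from 1.13 ± 0.207 to 15.0 ± 10.5 FPKM.

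Zona glomerulosa genes fell in 5 of 14 cases (5 adjusted over the list alone, camera adjusted p = 0.00026, and adjusted p = 0.33 with an estimated correlation), with Vsnl1 down from 21.1 ± 2.41 to 0.898 ± 0.722 FPKM. The list stood at −1.23, −0.52, −4.74 and −1.07 log2 relative to before in 24 h replicates 1 to 4, and without replicate 3 the camera adjusted p was 0.01. Cholesterol synthesis genes fell in 5 of 22 cases (10 adjusted over the list alone, camera adjusted p = 0.00026, and adjusted p = 0.43 with an estimated correlation). The mean of that list in before replicate 1 (−0.73 log2 relative to before) lay below those of 24 h replicates 1 to 3 (−0.52, −0.58 and −0.66). Of 11 steroid synthesis genes 1 fell, Hsd3b1 (log2 −1.70, SE 0.35), and of 10 cortical identity genes Nr5a1 and Gata6 fell (2 rose and 4 fell adjusted over the list alone). Nr5a1 was not called when any 1 library but 24 h replicate 2 was left out (adjusted p from 0.054 to 0.11). Gata6 was not called without before replicates 2, 3 or 4 or 24 h replicates 1 or 4 (adjusted p from 0.071 to 0.11). The steroid synthesis list (1 adjusted over the list alone, camera adjusted p = 0.12, and adjusted p = 0.63 with an estimated correlation) stood at −0.04, 0.44, −5.07 and 0.09 log2 relative to before in 24 h replicates 1 to 4. With replicate 3 kept, its camera adjusted p was 0.04 without replicate 2 and 0.043 without replicate 4, and it was 0.96 without replicate 3. Clock genes fell in 5 of 15 cases (8 adjusted over the list alone), with Per2 at log2 −1.71 (SE 0.35), and the list was not called (camera adjusted p = 0.078, and adjusted p = 0.33 with an estimated correlation) except without before replicate 3 or 24 h replicate 4 (0.043 for each). Medulla markers had 0 of 15 called (edgeR, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 by DESeq2) and were called lower as a list (camera adjusted p = 0.0044, and adjusted p = 0.55 with an estimated correlation). Red blood cell genes had 0 of 5 called (edgeR, 4 adjusted over the list alone, 4 at an unadjusted p under 0.05, 4 by DESeq2) and were called lower as a list (camera adjusted p = 0.01, and adjusted p = 0.43 with an estimated correlation). Neither list was called without replicate 3 (camera adjusted p = 0.12 and 0.08), in which they stood at −5.29 and −4.89 log2 relative to before.

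Endothelial genes rose in 1 of 10 cases (Cdh5, 0 adjusted over the list alone, camera adjusted p = 0.26, and adjusted p = 0.81 with an estimated correlation), and in 7 of 10 without replicate 3 (camera adjusted p = 0.00029). Cdh5 was not called without any 1 of the before libraries or 24 h replicates 2 or 4 (adjusted p from 0.055 to 0.13), with a log2 fold change of 0.83 in all libraries and 0.50 without 24 h replicate 4. Cholesterol transfer genes rose in 4 of 12 cases and fell in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.26). Genes of the ACTH response rose in 3 of 15 and fell in 1 (3 and 3 adjusted over the list alone, 0.66). Of 11 glucocorticoid-induced genes Tsc22d3 fell (3 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.66), with a list median of −0.07 and a mean of 0.03. Of 14 lipid storage genes Hilpda rose (log2 1.63, 1 adjusted over the list alone, camera adjusted p = 0.95). Without 24 h replicate 4 its log2 fold change was 0.86 (adjusted p = 0.058), and without before replicate 5 the adjusted p was 0.05. Of 3 X-zone markers Thrb fell (1 adjusted over the list alone, 0.31). Cortical identity was not called as a list (camera adjusted p = 0.15). Of 2 gonad genes tested Sox9 rose (log2 1.06, SE 0.30, adjusted p = 0.027, 2 adjusted over the list alone). It was not called without before replicates 2, 3, 4 or 5 or 24 h replicate 4 (adjusted p from 0.051 to 0.074). Of 2 liver and kidney genes 0 were called by edgeR (0 adjusted over the list alone) or DESeq2 and 0 passed an unadjusted p under 0.05. Fat-cell genes had 0 of 10 called (edgeR, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by DESeq2, camera adjusted p = 0.66), with a median of 0.46 and a mean of 0.33 against a camera direction of lower. Respiratory chain genes had 0 of 21 called (edgeR, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 by DESeq2, camera adjusted p = 0.26). By camera 16 lists were called, 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 14 by fry, and 16 of 100 splits of the same libraries gave at least 16.

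Other large changes were rises of Clec7a, Atp6v0d2, Gpnmb, Ear2 and Il1a and falls of A2m, Akr1d1, Mybpc1, Xrra1, Elfn1, Entpd3 and Rdh1. Akr1d1 stood at 17.7 ± 23.7 FPKM at 24 h (adjusted p = 0.038) and was not called when any 1 of 7 libraries was left out (before 1 to 5 and 24 h 2 and 4, adjusted p from 0.052 to 0.08). Ear2 has near-identical copies, so its value is uncertain.

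Replicate 3 at 24 h carried 1.07 FPKM of Cyp11b1 and 2.42 of Cyp21a1, genes of corticosterone synthesis chosen here after their values were seen, against at least 969.4 and 1391 in the other 24 h libraries. It also held 2.36 FPKM of Th, a catecholamine enzyme, and replicate 4 held 14.9, against at least 182.5 in replicates 1 and 2. Both had little Xist, a transcript of the inactive X chromosome (0.0374 and 0.0101 FPKM), which stood between 17.7 and 41.6 FPKM in the other 11 libraries. Comparisons with the 24 h group thus set libraries with and without Xist against libraries that all had it. No covariate for that difference was fitted. Without replicate 3, 3998 genes were called, and with only replicates 1 and 2 at 24 h 2960 were, 1949 of them among the 2708.

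**Figure D3:**
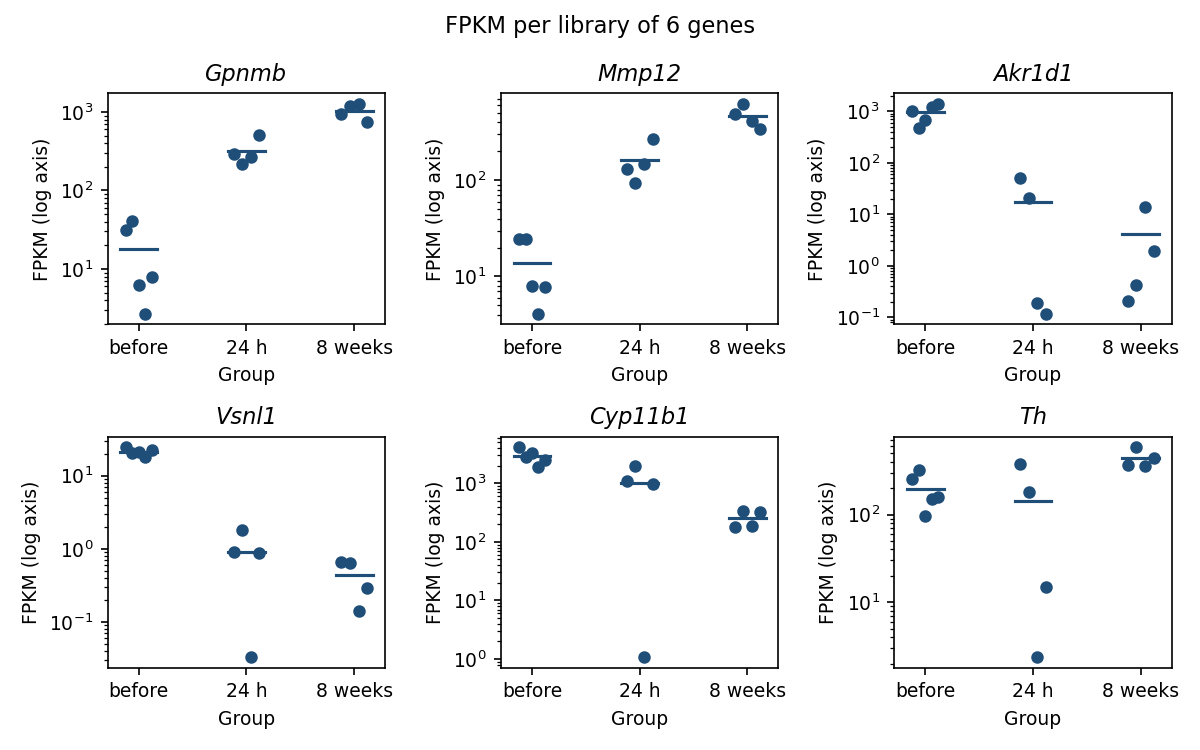
FPKM per library of Gpnmb, Mmp12, Akr1d1, Vsnl1, Cyp11b1 and Th on log axes. Points are libraries and lines are means. Replicate 3 at 24 h is the lowest point for Cyp11b1 (1.07 FPKM) and Th (2.36 FPKM).

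The comparison of 8 weeks with 24 h asks how the early and late states differ. By single genes, 8 of 12 of lipid-laden macrophages and 14 of 21 of the respiratory chain were higher at 8 weeks. Of the lists that went the other way, 8 of 12 interferon, 11 of 13 proliferation and 5 of 15 endoplasmic reticulum stress genes were lower. Spp1 rose from 208 ± 88.6 to 889 ± 289 FPKM and Irf7 fell from 75.4 ± 32.2 to 13.7 ± 2.49 FPKM (n = 4 in both groups). Of 14078 genes, 2923 were called, 1428 higher and 1495 lower, and without a scaling factor 1181 higher and 2093 lower.

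Of 12 genes of lipid-laden macrophages, 8 rose (11 adjusted over the list alone, camera adjusted p = 1.9e-05, and adjusted p = 0.61 with an estimated correlation). Of 21 respiratory chain subunits, 14 rose (19 adjusted over the list alone, camera adjusted p = 1.9e-07, and adjusted p = 0.61 with an estimated correlation). Ucp1 stood at 128.8 ± 134 FPKM at 24 h against 769.8 ± 474 at 8 weeks, and both Ucp1 (0.116 FPKM) and the respiratory chain list (−0.80 log2 relative to before) were lowest in 24 h replicate 3. Lymphocyte genes rose in 6 of 12 cases (8 adjusted over the list alone, camera adjusted p = 0.008, and adjusted p = 0.69 with an estimated correlation), with the B cell genes Cd79a and Ms4a1 among them. Without 8-week replicate 1 the log2 differences of these 2 genes went from 3.40 to 2.09 and from 3.71 to 1.56, and Ms4a1 was not called (adjusted p = 0.11), nor without 24 h replicate 4 (0.055). Cholesterol synthesis genes rose in 6 of 22 cases (6 adjusted over the list alone, camera adjusted p = 0.0085, and adjusted p = 0.72 with an estimated correlation), among them Acat2, and the list was not called without 24 h replicate 4 (camera adjusted p = 0.058). Lipid storage genes rose in 4 of 14 cases and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.025, and adjusted p = 0.62 with an estimated correlation). Glucocorticoid-induced genes rose in 2 of 11 cases, Tsc22d3 and Pdk4 (2 adjusted over the list alone, camera adjusted p = 0.031, and adjusted p = 0.61 with an estimated correlation). Pdk4 was not called without 24 h replicate 2 or 8-week replicates 2 or 4 (adjusted p = 0.068, 0.061 and 0.077). Medulla genes were called higher as a list, with 0 of 15 called by edgeR (0 adjusted over the list alone, camera adjusted p = 3.2e-05, and adjusted p = 0.62 with an estimated correlation). Red blood cell genes rose in 2 of 5 cases (4 adjusted over the list alone, camera adjusted p = 0.008, and adjusted p = 0.61 with an estimated correlation). Fat-cell genes rose in 1 of 10 (0 adjusted over the list alone, camera adjusted p = 0.008, and adjusted p = 0.72 with an estimated correlation). Medulla and red blood cell genes were lowest in 24 h replicates 3 and 4, and the fat-cell list stood at −6.26 log2 relative to before in 24 h replicate 3 and between 1.01 and 2.33 in the other 24 h libraries. Of the medulla markers 6 passed an unadjusted p under 0.05 and 3 were called by DESeq2. Without 24 h replicate 3 the lymphocyte (camera adjusted p = 0.058), lipid storage (0.081) and glucocorticoid-induced lists (0.058) were not called. The last was also not called without 24 h replicates 1 or 2 or 8-week replicate 2 (0.084, 0.056 and 0.055).

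Proliferation genes fell in 11 of 13 cases (12 adjusted over the list alone, camera adjusted p = 1.9e-05, and adjusted p = 0.61 with an estimated correlation), and with only 24 h replicates 1 and 2 in 1 (camera adjusted p = 0.012). Interferon genes fell in 8 of 12 cases (10 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00015, and adjusted p = 0.61 with an estimated correlation). Endoplasmic reticulum stress genes fell in 5 of 15 cases (5 adjusted over the list alone, camera adjusted p = 0.031, and adjusted p = 0.72 with an estimated correlation), including Ddit3, and the list was not called without 24 h replicates 1, 2 or 4 or 8-week replicate 4 (0.1, 0.14, 0.13 and 0.078). Cortical identity genes fell in 4 of 10 cases (4 adjusted over the list alone, camera adjusted p = 0.031, and adjusted p = 0.61 with an estimated correlation), led by Nr5a1 (log2 −2.36, SE 0.33), and this list was not called without 24 h replicates 1 or 3 or 8-week replicate 3 (camera adjusted p = 0.055, 0.16 and 0.081), nor without a scaling factor (0.071). Of 11 steroid synthesis genes 5 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.16, and adjusted p = 0.72 with an estimated correlation), and without 24 h replicate 3, 9 fell and 1 rose (camera adjusted p = 5.6e-05). Of 14 zona glomerulosa genes 3 fell and 2 rose (3 and 2 adjusted over the list alone, camera adjusted p = 0.28, and adjusted p = 0.77 with an estimated correlation), and without that library 9 fell and 2 rose (0.0012). Endothelial genes had 0 of 10 called (edgeR, 0 adjusted over the list alone, 4 at an unadjusted p under 0.05, 3 by DESeq2, camera adjusted p = 0.051, and adjusted p = 0.72 with an estimated correlation), and 10 of 10 fell without that library (1.7e-05). That list was also called without 8-week replicate 4 (0.032) or a scaling factor (0.045).

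Macrophage genes rose in 3 of 15 cases and fell in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.23), and the list was not called. NRF2 targets rose in 1 of 12 cases and fell in 3 (1 and 4 adjusted over the list alone, camera adjusted p = 0.17). Targets of p53 rose in 1 of 12 and fell in 3 (2 and 3 adjusted over the list alone, 0.4). Genes of the ACTH response rose in 2 of 15 cases and fell in 3 (2 and 3 adjusted over the list alone, camera adjusted p = 0.61). Clock genes rose in 1 of 15 (1 adjusted over the list alone, 0.71). Cholesterol transfer genes rose in 1 of 12 and fell in 3 (1 and 3 adjusted over the list alone, 0.59). LXR targets rose in 2 of 10 and fell in 3 (2 and 4 adjusted over the list alone, 0.37). MHC class II genes had 0 of 7 called by edgeR (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by DESeq2, camera adjusted p = 0.16, and adjusted p = 0.75 with an estimated correlation), and the list was called without 8-week replicate 4 (0.043). By edgeR 0 of 10 capsule genes (0 adjusted over the list alone, 4 at an unadjusted p under 0.05, 1 by DESeq2, camera adjusted p = 0.25) were called. By edgeR 0 of 12 fibrosis genes (0 adjusted over the list alone, 3 at an unadjusted p under 0.05, 2 by DESeq2, 0.77) and 0 of 3 X-zone markers (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by DESeq2, 0.89) were called. By edgeR 0 of 2 gonad genes (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by DESeq2) and 0 of 2 liver and kidney genes (2 adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 by DESeq2) were called. The median, mean and camera direction differed in sign for the ACTH response, cholesterol transfer, fibrosis, LXR target and X-zone lists. By camera 13 lists were called, 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 9 by fry, and 5 of 35 splits of these libraries gave at least 13.

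Of the 8 largest rises, Cyp2c44, Upp2, Ahsg, Vtn and H2-Q10 were not called without 8-week replicate 3 (log2 2.15, 1.21, 2.46, 2.37 and 3.22, adjusted p = 0.21, 0.43, 0.16, 0.2 and 0.073). That library held 13280 FPKM of the liver gene Alb against at most 6.64 in the other 8-week libraries. In that replicate Ahsg reached 2421 FPKM and Vtn 424.6. Cyp2c44 and Ahsg were also not called without 24 h replicates 2 or 4, Upp2 and Vtn without 24 h replicates 1, 2 or 4, and H2-Q10 without 24 h replicate 4 (adjusted p from 0.052 to 0.072). Igj was not called without 24 h replicates 2 or 4 or 8-week replicates 1 or 2 (adjusted p from 0.051 to 0.098). Prl8a2, Igj and Rbp4 were the other rises. H2-Q10 belongs to a family of near-identical genes and is uncertain. The largest falls were Bcat1, Bean1, Hmga2, Jsrp1, Kcnu1, Mlf1, Kcnd2 and Srd5a2, and Bcat1 (32.28 FPKM), Hmga2 (4.353), Mlf1 (53.35) and Kcnd2 (10.35) were highest in 24 h replicate 3. Without it Mlf1 was not called (log2 −1.30, adjusted p = 0.06), nor without 8-week replicates 2, 3 or 4 (0.059, 0.053 and 0.052). Kcnd2 went from log2 −4.18 to −2.13 without 24 h replicate 3. With only these 2 groups in the fit 973 genes were called, and without 8-week replicates 1, 2 or 4 in turn 1782, 1808 and 1941.

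Changes from before at 24 h and at 8 weeks overlapped. Among the 14078 genes, 1233 were called higher and 610 lower at both times, and 20 in opposite directions, against 363.2 and 153.3 for independent lists of these sizes. The Pearson correlation of fold changes across genes, which are not independent, was 0.59 with a covariance of 0.56. In 20 simulated sets of unchanged groups that shared their before libraries the means were 0.44 and 0.04. These sets took the spread of the real before libraries, which was narrower than that at 24 h. With the before libraries split between the comparisons, 721 or 1093 genes were shared in direction and the correlation was 0.48 or 0.50.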

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

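The tests of depth, medulla markers, gonad genes, Xist and the endothelial markers were chosen after the results they bear on were seen, and the tests of splits and of liver RNA before.

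A library stood far from the others of its group in 47 of the 216 groups of values tested, where chance gives about 1 in 20, or 10.8, for normally distributed values. The number beside each is the gap to the nearest library divided by the range of the group. Many of these share a library, so they are not separate events. Genes were read as FPKM, not on a log scale, and were named for large changes. The 10.8 therefore need not be the number chance gives here. Replicate 3 at 24 h was lowest in the list means of the ACTH response (0.8553), fat cells (0.8463), cholesterol transfer (0.8592), lipid storage (0.8467), macrophages (0.8304), the respiratory chain (0.8632), steroid synthesis (0.9129), endoplasmic reticulum stress (0.8646) and the zona glomerulosa (0.8318). The same library was highest for Klk1 (0.9701), Nr0b1 (0.9576), Rdh1 (0.8766), Bcat1 (0.9534), Hmga2 (0.896), Mlf1 (0.9892) and Kcnd2 (0.9572). Replicate 4 at 24 h was lowest for cholesterol synthesis (0.8293).

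At 8 weeks, replicate 3 was highest for Akr1d1 (0.8776), Cd5l (0.8878), Rdh1 (0.9444), Cyp2c44 (0.9996), Upp2 (0.9961), Ahsg (0.9858), Vtn (0.9955), H2-Q10 (0.9784) and Rbp4 (0.8765). Replicate 1 was highest for Klk1 (0.9729), A2m (0.9112) and Igj (0.8684). Replicate 2 was highest for capsule genes (0.84) and Bcat1 (0.8294) and lowest for red blood cell genes (0.876). Before TAM, replicate 5 was highest for Cyp2c44 (0.8202), Upp2 (0.8881), Ahsg (0.9648), Vtn (0.9822), H2-Q10 (0.8662) and Rbp4 (0.8063). Replicate 1 was lowest for fat cells (0.8842), lipid storage (0.8171) and Jsrp1 (0.7633) and highest for A2m (0.9085), Igj (0.7903) and Bcat1 (0.725). Replicate 3 was lowest for clock genes (0.7391) and highest for Bean1 (0.8519) and Mlf1 (0.7906).

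Replicate 3 at 24 h stood apart from the other 24 h libraries, with a median correlation of 0.811 with its group, and its listed total of 27.3 M reads, the highest of the 13 libraries, argues against low depth. Its medulla markers lay at −4.28 log2 relative to the mean of the other 24 h libraries, which argues against a loss of cortex cells alone. Other tissue in the sample stays open, since of 18 ovary genes only Inhbb and Fst were listed (median 3.1 log2 higher) and of 14 testis genes 4 were (median 1.37), too few to decide. The filter on listed transcripts leaves out any gene with reads in that library alone, so few could be listed whatever the tissue. Xist, at 0.0374 FPKM there and between 17.7 and 41.6 in 11 other libraries, goes against ovary, and Inhbb was high in replicate 4 as well (14.4 against 20.5 FPKM). Gdf9, an oocyte growth factor listed with the 24 h libraries alone, had 2825 reads there and at most 40 in the others, and 453 transcripts were listed with the 24 h libraries alone.

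Macrophage and lymphocyte markers rose at 8 weeks while steroid synthesis genes fell. A lower share of cortex RNA would raise the cell types outside the cortex alike. The macrophage list lay at least 1.93 log2 above the endothelial list in each 8-week library. That gap cannot decide, since vessels also run within the cortex and their RNA may fall with it. The medulla list (1.32, 1.61, 1.48 and 1.67 log2 relative to before in 8-week replicates 1 to 4) and the capsule list (1.71, 2.13, 1.68 and 1.63) were higher too. Both lay close to the macrophage list in replicate 4 (1.93) and below it in replicates 1 to 3 (2.35, 2.43 and 2.63). The list of lipid-laden macrophages, looked at after its values were seen, stood at 4.36, 4.55, 4.4 and 4.04 log2 in replicates 1 to 4. That lies above the medulla and capsule lists in each 8-week library. It argues against a lower cortex share as the whole source of the rise of that list. For the macrophage and lymphocyte lists a lower cortex share as a cause stays open. Liver RNA in before replicate 5 and 8-week replicate 3 as the source of the macrophage rise is argued against by 13 of 15 macrophage genes being called higher without both. That test did not cover the lymphocyte and steroid synthesis genes. Without 8-week replicate 3 alone the steroid synthesis list was not called (camera adjusted p = 0.052). The deletion and the time since TAM stay open, untested, since the design does not separate them.

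Libraries without Xist at 24 h (replicates 3 and 4) were weighed as the source of the 24 h calls. With replicates 1 and 2 only, 72% of the genes called at 24 h were called in the same direction, which argues against those libraries as the whole source. The sex of the mice is not in the labels used here, and no biological explanation was tested.

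The change from before differed between 24 h and 8 weeks for 2923 genes and 13 lists by the direct test. For genes, only the real split of the libraries gave as many as were called. It was 1 of 100 splits for 8 weeks against before (5193, highest other 2135) and 1 of 100 for 24 h against before (2708, highest other 959). For 8 weeks against 24 h it was 1 of 35 (2923, highest other 46). Chance is thus an unlikely source of these counts, though so few splits cannot exclude it. The highest other split for each comparison with before set before replicates 2 to 5 against before replicate 1 and the later libraries, close to the real split. For camera's counts of lists chance cannot be excluded: 33 of 100 splits gave at least the real 11 (highest other 16), 16 of 100 at least 16 (highest other 20) and 5 of 35 at least 13 (highest other 15).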

How the results depend on the processing

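Alternatives that leave out 24 h replicate 3 (for 8 weeks against before), 24 h replicates 3 and 4, or before replicate 5 with 8-week replicate 3, that use all transcripts listed for the groups compared, single transcripts or no scaling factor, list tests within the groups compared, and readings of the overlap and correlation under the alternatives were chosen after seeing the data. Star, as a gene sum, fell against before at both times under each alternative that gave it a value. It was not read at the level of transcripts or at 2-fold, and with all listed transcripts only at 8 weeks. Of the named genes called in the fit of all libraries, 102, 87 and 89 (8 weeks against before, 24 h against before, 8 weeks against 24 h), 11, 22 and 32 lost the call when some library was left out, and 14, 31 and 52 under some alternative, and 0 changed sign. Among genes that were not called, Alb at 24 h against before changed sign under the replicate block (3.3) and without before replicate 5 (1.06) or before replicate 5 and 8-week replicate 3 (1.07), against −5.90 with all libraries (−9.09 to 1.06 with 1 library left out). So did Gata4 at 8 weeks against 24 h with quality weights (0.1) and without 24 h replicate 3 (0.53) or replicates 3 and 4 (0.36), against −3.59 (−3.99 to 0.53 with 1 library left out). The cause was not tested.

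Leaving out 1 library at a time gave 4153 to 6706 genes for 8 weeks against before, 1851 to 3998 for 24 h against before and 1782 to 4300 for 8 weeks against 24 h, and 8 to 14, 15 to 18 and 10 to 14 lists. Star ranged from −4.71 to −4.41, from −3.87 to −2.98 and from −1.62 to −0.68 (adjusted p from 0.0064 to 0.53 for the last), the overlap of calls from 1345 to 2576 and the correlation from 0.48 to 0.61. At 2-fold 2850, 1567 and 1532 genes were called. With only the groups compared 973 genes were called for 8 weeks against 24 h, and 7895 for 8 weeks against before over all listed transcripts. Replicate numbers did not pair the libraries (correlations of deviations from −0.13 to 0.28, 2 of 12 over 0.1, 1 of 12 best with its own number), and the replicate block gave 3848, 1312 and 1661 genes and an overlap of 1029. Quality weights, which were 0.10 and 0.24 for 24 h replicates 3 and 4, gave 8101 and 5378 genes against before, Star at −1.60 between 8 weeks and 24 h (adjusted p = 0.0067), an overlap of 3712 and a correlation of 0.72. Without 24 h replicates 3 and 4 that Star difference was −1.94 (adjusted p = 0.002) and the correlation 0.66. Without before replicate 5 and 8-week replicate 3, 1727 and 1551 genes were called in the comparisons with 24 h and the overlap was 1217. Splitting the before libraries gave overlaps of 721 and 1093 and correlations of 0.48 and 0.50. With an estimated correlation 0, 0 and 0 lists were called by camera (3, 4 and 0 at an unadjusted p under 0.05, 14, 14 and 9 by fry). Without a scaling factor the median log2 fold change moved by −0.127 for 8 weeks against before, and calls split into 2424 higher and 3054 lower, against 2882 and 2311 with TMM, and for 8 weeks against 24 h into 1181 and 2093, against 1428 and 1495. The cause of these shifts was not tested. List tests were not run with DESeq2, quality weights, single transcripts or the filters. A sex covariate and settings for FPKM tests were not run. The first was not read from Y-linked genes, which are not listed, nor from Xist. The second were left out because expected counts were tested.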

Other observations

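The genes described here were chosen after their values were seen. Among transcripts listed with the 24 h libraries alone, 15 of 453 were at least 10 times higher in replicate 3 than in each of the other 3. Transcripts with reads in replicate 3 alone could not pass the filter and are not among the 453. Besides Gdf9 these included Dppa3, a gene of oocytes and early embryos (917 reads, at most 20 in the others), and Zfp57, an imprinting regulator (1108 reads, at most 35). The same library held 83.04 FPKM of Gata4 and 246 of Inha, both genes of gonadal somatic cells, against at most 1.652 and 54.48 in the other 24 h libraries.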
